A study of Mus musculus with 16 samples.

How the data were processed

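RNA was sequenced from 3 populations of mouse thymic epithelial cells, the stromal cells that select developing T cells. The labels call them cortical thymic epithelial cells (cTEC), medullary cells low in MHC class II (mTEClo) and medullary cells high in MHC class II (mTEChi). Each came from wild-type (WT) mice and from mice lacking Psmb11 (KO), the gene of the thymoproteasome subunit beta5t, which cTEC express. Per the labels' protocols, CD45-negative EpCAM-positive cells were sorted as cTEC when Ly51-positive and UEA1-negative and as mTEC when Ly51-negative and UEA1-positive. Libraries were made with a TruSeq RNA kit, which does not mark the strand, and read on a HiSeq2000. The labels conflict on the animals. The series description and the sample labels state an age of 6 to 8 weeks, and the former 11 thymi, while the extraction protocol states 7 days and 14 mice. How many animals a library pools is not stated.

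The authors deposited a table of read counts per gene symbol, raw and not normalised, with 23420 gene entries and, at its end, entries for reads assigned to no gene. Per the submitters' processing notes, CASAVA 1.8.2, HTSeq 0.5.4p1 and the mm10 genome were used; the aligner, its settings and the annotation are not stated. Reads in no gene made up 13.7% to 30.4% of a library, highest in cTEC KO 1, and reads in overlapping genes 0.541% to 0.887%. The authors also deposited RPKM values, reads scaled by gene length and by library total, for 23063 genes with coordinates, without the gene lengths or read totals they divided by. Of those symbols, 21291 matched RefSeq on GRCm38, and 63.6% of the matched starts lay within 5 bases of the RefSeq start.

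Counts from all 16 libraries were fitted with edgeR 4.0.16 in R 4.3.3. The fit had 6 group means, TMM scaling, the filterByExpr filter (20126 genes tested) and a quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are given as CPM, counts over the library total scaled by TMM. Standard errors (SE) of log2 fold changes came from the F statistic, and ± gives an SD. The 9 comparisons were KO against WT in each population, the 3 differences between those effects, and the WT populations against each other. All groups share 1 estimate of the spread in this fit, because 2 libraries per cTEC group leave 2 residual degrees of freedom on their own. The p-values measure the spread between libraries, which the fit takes as independent samples. The labels state 11 thymi or 14 mice for 16 libraries. Whether libraries of different populations came from the same animals is not stated, and the fit does not account for it.

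Of 28 gene lists fixed before the data were examined, 27 had at least 2 members tested; the list of mitochondrial genes had none in the table. The table held 402 of the list genes and lacked 18, and 13 genes stood in more than 1 list. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists within a comparison), again with an estimated correlation, and with fry. Psmb11 was left out of the list tests of KO against WT. Named genes followed a rule fixed before the data were examined. For KO against WT the rule took Psmb11 first, and then genes past the threshold with a log2 fold change of at least 1 in size, groups whose CPM do not overlap, a mean of at least 5 CPM in the higher group and an established symbol. Of these it took the 6 largest folds and the 6 smallest p-values per direction (5 and 3 between WT populations), and up to 4 members of each list with the smallest p-values. Where no gene passed, it took the smallest p-values alone. Some genes that the rule took are not reported here.

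Genes detected were those with at least 1 count after thinning every library to the lowest total, 64753610 counts, averaged over 20 thinnings, and were compared with two-sided exact permutation tests. For a gene at 0 in every library of a group, the fold was computed against a floor of 3 counts over the group. Between 1 and 3 counts, the ratio is given with its 95% counting interval. These bounds and intervals cover counting error only, since reads copied by PCR are not independent molecules.

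The shared fit and the fits of a population alone were tested on simulated counts with 100 genes changed per fold size, or 200 for the differences between effects. In cTEC, KO against WT, the shared fit recovered 83% of 2-fold and 92% of 4-fold changes among 19922 genes, but also called 2292 unchanged genes. A fit of the 4 cTEC libraries alone recovered 44% and 75% among 15477 genes, with 6 unchanged genes called. With no effect simulated in 5 simulations, the shared fit called a median of 2219 genes in cTEC (range 2146 to 2316), and the fit of cTEC alone a median of 0. In mTEClo the shared fit recovered 78% of 2-fold and 92% of 4-fold changes (14 unchanged genes called), and in mTEChi 81% and 95% (0 called). Fits of these populations alone recovered 97% and 98% in mTEClo (19 called) and 100% at both sizes in mTEChi (12 called). The simulated counts held 200 changed genes per population, which loosens the Benjamini-Hochberg cutoff. Recovery may therefore be lower where few genes change. In the data the shared fit missed the fall of Psmb11 in mTEClo and in mTEChi (log2 fold change -2.92 and -3.34). For the differences between effects, 66.5% and 90% were recovered in cTEC minus mTEClo (1042 called), 69% and 90% in cTEC minus mTEChi (1006 called), and 70.5% and 91% in mTEChi minus mTEClo (6 called). Between WT populations, recovery was 80% and 92% for cTEC against mTEClo (1513 called), 80% and 95% for cTEC against mTEChi (1547 called), and 70% and 94% for mTEChi against mTEClo (2 called). Of 27 lists, 2 were called in cTEC with no effect simulated, and a list of 13 genes raised 2-fold was recovered. Genes were drawn independently in these counts, so how often lists of correlated genes are called without an effect was not tested.

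The alternatives planned before the data were examined were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter, a fit of the groups compared alone, the replicate number as a block, RPKM in limma with a pseudocount of 1 or 0.1 or without a filter on low values, and leaving out each library. A pair of further fits was added after the spread among the cTEC libraries had been seen, namely limma voom with a weight per library and with a variance per population. In cTEC, single genes are therefore described first that passed both the shared fit and the fit with a weight per library. Counts of list members past the threshold are from the shared fit.

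In the count table, 27 gene names had been turned into dates and were tested but not named. Reads that fit near-identical copies (kallikreins, Reg3, Mup and H2 genes) may have been split or dropped, so values of such genes are uncertain. Reads from a gene and from its antisense partner cannot be told apart. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.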

Results

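The transcriptomes of cTEC, mTEClo and mTEChi from WT and Psmb11 KO mice were compared to ask what loss of the thymoproteasome subunit beta5t does to thymic epithelial cells. There were 16 libraries, with 2 per genotype for cTEC and 3 per genotype for mTEClo and for mTEChi. Total gene counts were 74148029 and 67810047 in cTEC KO and 94959679 and 92178798 in cTEC WT. They ranged from 95777929 to 115251165 in mTEClo and from 64753610 to 146707262 in mTEChi, so 3 counts correspond to at most 0.0461 CPM in any library.

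Psmb11 (chromosome 14, 54625310 to 54629556, mm10) has a coding transcript of 1 exon, with the coding sequence at 54625327 to 54626232 and the stop codon and 3' UTR at 54626233 to 54629556. The annotation holds a further transcript that starts upstream at 54621433. In cTEC it fell from 160 ± 19.6 CPM in WT to 1.05 ± 1.49 CPM in KO (SD, n = 2 each), a log2 fold change of -7.22 (SE 0.90, adjusted p = 1.12e-04 by edgeR). Read counts were 15214 and 12756 in the WT cTEC libraries and 157 and 0 in the KO ones. In mTEClo, WT libraries held 9.62 ± 2.58 CPM and KO libraries 1.27 ± 0.285 CPM (n = 3 each), with counts of 707, 1220 and 778 against 177, 111 and 115. In mTEChi the levels were 9.84 ± 1.71 and 0.972 ± 0.224 CPM (n = 3 each), with counts of 889, 1672 and 598 against 74, 87 and 172. The log2 fold changes of -2.92 (SE 0.61, adjusted p = 0.653) in mTEClo and -3.34 (SE 0.63, adjusted p = 1) in mTEChi did not pass the shared fit, although the genotypes did not overlap. Both passed in fits of each population alone and in both voom fits, whereas in cTEC Psmb11 missed the threshold in those fits.

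**Figure D1:**
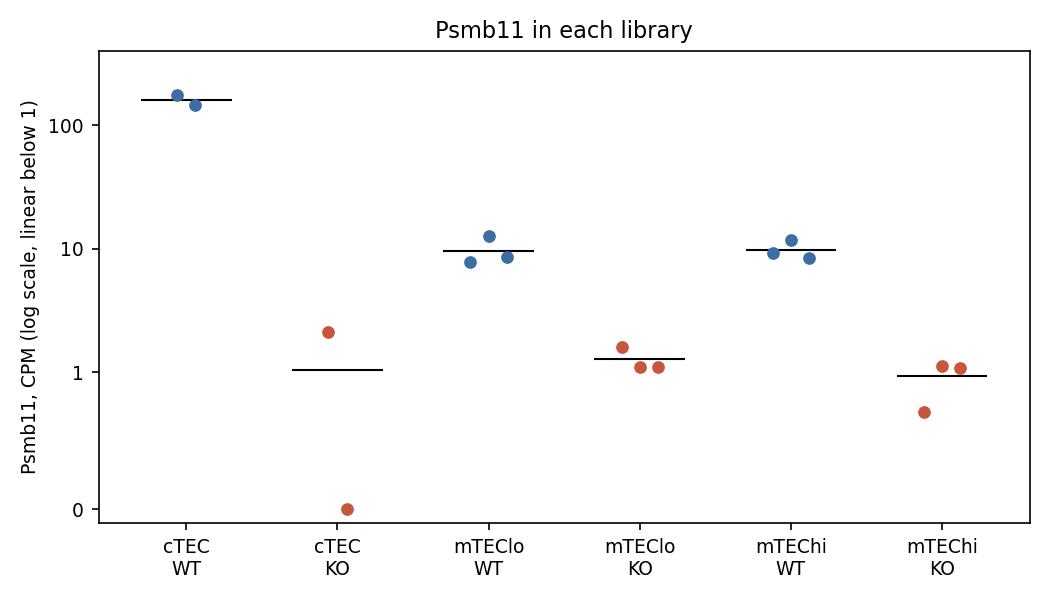
Psmb11 in CPM (log scale, linear below 1) for each library by population and genotype; points are libraries and bars are group means. Every KO library lies below every WT library of its population, with WT cTEC at 160 CPM on average and WT mTEClo and mTEChi at 9.62 and 9.84.

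In cTEC, the shared fit called 14 of 17 medullary markers and 19 of 28 tissue-restricted antigen genes higher without Psmb11 (camera adjusted p = 1.66e-14 and 2.26e-12, and 0.0554 and 0.125 with an estimated correlation). Over all 20126 genes tested it called 2650 higher and 2050 lower, and a median of 2219 with no effect simulated. Counts of list members that rose or fell in cTEC, here and below, are calls of this fit and may include calls made without an effect. The following 5 genes were named for their small p-values and not for a list, although Iapp is also among the tissue-restricted antigens. The calcium-binding protein gene S100g (chromosome X, 162961992 to 162964599) rose from 0.848 to 14.7 CPM, a log2 fold change of 4.11 (SE 0.16, adjusted p = 9.67e-09). Iapp, the islet hormone amylin (chromosome 6, 142298425 to 142303819), rose by 5.12 (SE 0.23, adjusted p = 4.55e-08). The leukocyte surface gene Cd52 (chromosome 4, 134093538 to 134095073) rose by 2.06 (SE 0.10), and Srgn, which encodes the granule proteoglycan serglycin (chromosome 10, 62494428 to 62507755), rose by 1.76 (SE 0.10). Of the genes that fell, Scn1a, a sodium channel gene (chromosome 2, 66270782 to 66440837), went from 296 to 133 CPM, a log2 fold change of -1.16 (SE 0.15, adjusted p = 1.90e-04). These p-values are from the shared fit. By voom with a weight per library, adjusted p was 0.00208 for S100g, 0.0197 for Iapp, 4.74e-04 for Cd52, 1.04e-04 for Srgn and 0.00278 for Scn1a. By edgeR on the cTEC libraries alone it was 0.0687 for each of them.

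In all, 163 genes were higher and 7 lower in cTEC KO both in the shared fit and in the fit with a weight per library, among them 20 of the 93 genes that the naming rule took from those past the threshold. The fit with a weight per library was not run on simulated counts, so how many genes pass both fits without an effect is not known. Beside the genes above, the low-affinity IgE receptor Fcer2a (log2 fold change 1.99, SE 0.10), the adhesion gene Dscaml1 (1.98, SE 0.11) and the prostacyclin receptor Ptgir (5.58, SE 0.80) rose in both fits. Smoc2, a matricellular protein gene, and the noncoding RNA Snhg11 fell in both, the latter by 1.30 (SE 0.17). The shared fit alone called 4700 genes, 2650 higher and 2050 lower, of which 1780 and 412 changed at least 2-fold. An edgeR fit of the 4 cTEC libraries alone called 0 of 16423 genes, with 2104 at an unadjusted p under 0.05. That is more than the share of 0.05 expected with no effect, so its 0 does not show an absence of change. The count of the shared fit is too high to be read as a number of changed genes, because that fit called a median of 2219 genes with no effect simulated. The count was 8769 without cTEC KO 1, 5740 without cTEC KO 2, 2636 without cTEC WT 1 and 3181 without cTEC WT 2.

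**Figure D2:**
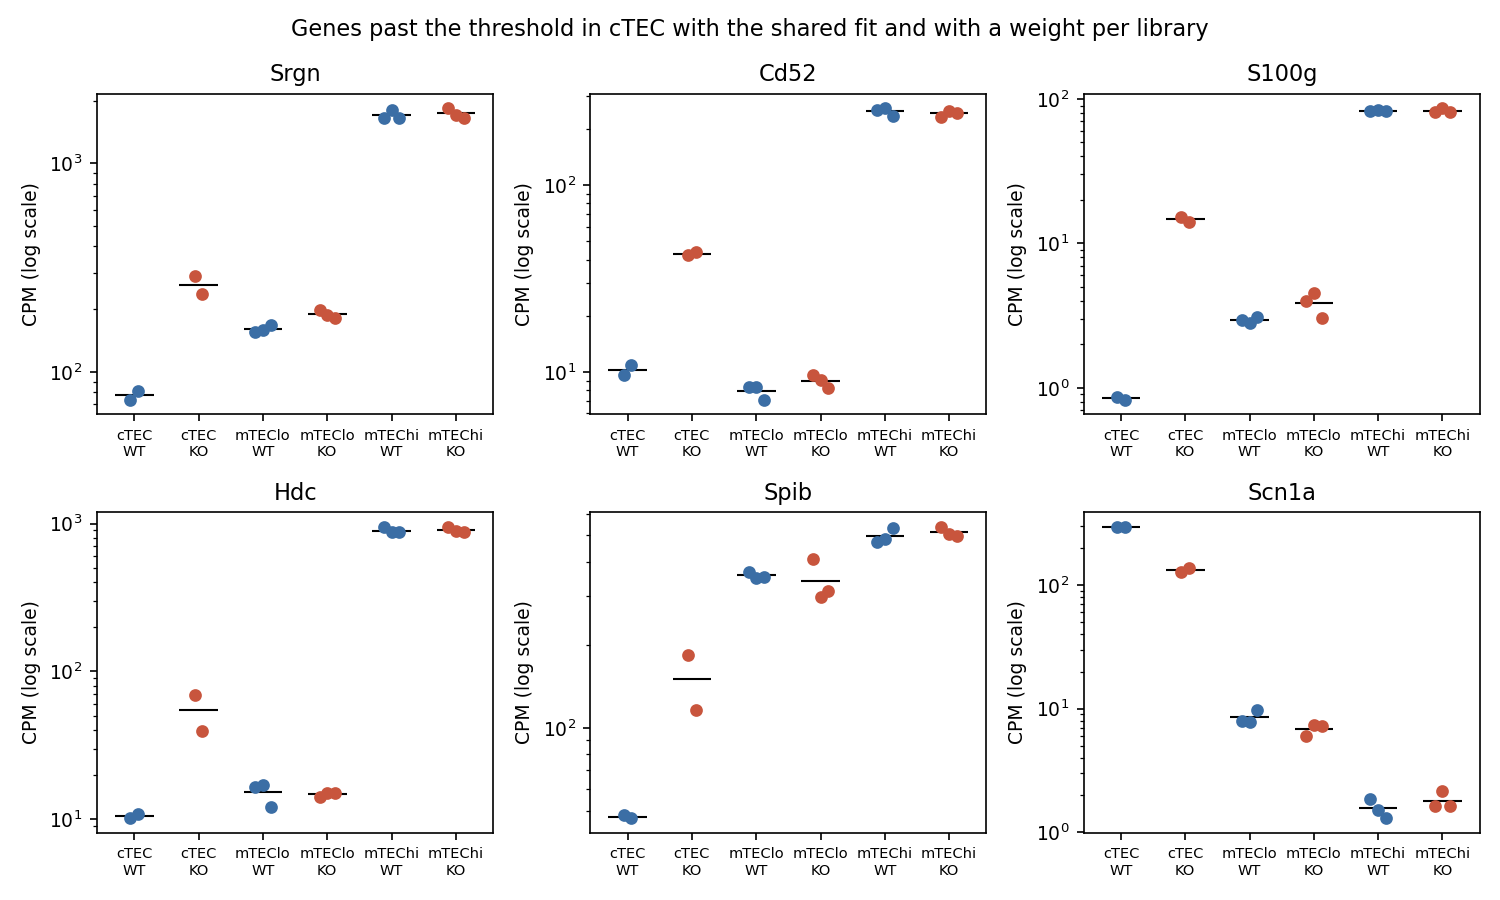
CPM (log scale) of 6 genes in each library by population and genotype; points are libraries and bars are group means. Srgn, Cd52, S100g, Hdc and Spib are higher and Scn1a lower in both cTEC KO libraries than in both cTEC WT libraries, and the first 5 are highest in mTEChi.

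Medullary markers rose as a group in cTEC KO: 14 of 17 rose and 0 fell (14 adjusted over the list alone), with a median log2 fold change of 0.98 and a camera adjusted p of 1.66e-14 (adjusted p = 0.0554 with an estimated correlation). They included the cathepsin S gene Ctss (1.31, SE 0.08), the costimulatory ligand Cd80 (1.82, SE 0.14), the histidine decarboxylase gene Hdc (2.37, SE 0.21) and the transcription factor Spib (1.66, SE 0.18), all 4 of which also passed with a weight per library. Hdc, for example, rose from 10.5 ± 0.544 CPM to 54.6 ± 21.5 CPM (n = 2 each), against 895 CPM in WT mTEChi. Aire, the regulator of tissue-restricted gene expression, had a log2 fold change of 2.63 (SE 0.35, adjusted p = 2.01e-04); it was outside the naming rule and was singled out after its value was seen.

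Tissue-restricted antigen genes, which medullary cells express to display peripheral self-proteins, rose in 19 of 28 cases and fell in 0 (21 adjusted over the list alone), with a median of 2.71 and a camera adjusted p of 2.26e-12 (adjusted p = 0.125 with an estimated correlation). The beta-casein gene Csn2 (2.79, SE 0.31), Resp18 of endocrine cells (2.63, SE 0.21) and the apolipoprotein gene Apoa1 (4.47, SE 0.60) rose in both fits. The incretin gene Gip, which is not on this list, had 3293 counts in KO and 2 in WT, a ratio of 2056 (95% counting interval 569 to 16982), but its KO libraries held 0.817 and 49.7 CPM and it did not pass with a weight per library. Of 11 genes of cornified, post-Aire medullary cells, 7 rose and 0 fell (9 adjusted over the list alone; camera adjusted p = 0.00130, adjusted p = 0.426 with an estimated correlation), with the smallest p-values for the desmoglein gene Dsg1a (2.82-fold higher) and the keratinocyte gene Krtdap (2.58-fold higher), of which Dsg1a alone passed with a weight per library. The larger folds of Krt77 and Sprr1b came from cTEC KO 1, where the keratin gene Krt77 had 1353 counts and Sprr1b 211, against 38 and 0 in cTEC KO 2 and at most 32 and 1 in a WT library. Without cTEC KO 1 the cornified list was not called (camera adjusted p = 0.383).

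Genes of thymic tuft cells, chemosensory cells of the medulla, rose in 12 of 13 cases (12 adjusted over the list alone), with a median of 1.45 and a camera adjusted p of 6.60e-14 (adjusted p = 0.164 with an estimated correlation). The G-protein subunits Gng13 (2.09, SE 0.19) and Gnb3 (1.54, SE 0.22), the phospholipase Plcb2 (1.54, SE 0.18) and the kinase Bmx (1.45, SE 0.21) rose in the shared fit and did not pass with a weight per library. In WT mTEClo, where this list was highest, Plcb2 stood at 319 CPM, against 129 ± 0.865 CPM in cTEC KO and 44.2 ± 7.29 CPM in cTEC WT (n = 2 each).

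Cortical markers went the other way. Of 14, 0 rose and 7 fell in cTEC KO (8 adjusted over the list alone), with a median of -0.40 and a camera adjusted p of 4.44e-04 (adjusted p = 0.426 with an estimated correlation). Kitl, the ligand of the Kit receptor on early thymocytes, fell by 0.88 (SE 0.14), Enpep, which encodes the Ly51 antigen used for the sort, by 0.86 (SE 0.15), and the endocytic receptor Ly75 by 1.04 (SE 0.20). None of these passed with a weight per library. Immediate early genes fell in 9 of 15 cases (12 adjusted over the list alone; camera adjusted p = 1.33e-05, adjusted p = 0.456 with an estimated correlation), among them Fosb by 0.64 (SE 0.17) and Klf2 by 0.88 (SE 0.23). Heat shock genes fell in 5 of 14 cases (5 adjusted over the list alone; camera adjusted p = 0.00182, adjusted p = 0.463 with an estimated correlation), among them the chaperonin gene Hspd1 by 0.79 (SE 0.13). Of 22 interferon response genes 8 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.0117, adjusted p = 0.426 with an estimated correlation). The antiviral gene Rsad2 fell by 1.01 (SE 0.12), while the chemokine gene Cxcl9 rose by 1.17 (SE 0.22). Of the genes named from these 3 lists, Fosb, Klf2, Hspd1, Rsad2 and Cxcl9, none passed with a weight per library, and Fosb and Klf2 kept their call in 3 and 1 of the 4 fits that left out a cTEC library. Without cTEC KO 1 the cortical, heat shock and interferon lists were not called (camera adjusted p = 0.421, 0.262 and 0.383).

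Other proteasome genes moved little in cTEC. Of the 5 immunoproteasome and activator subunits other than Psmb11, only Psme1 rose (0.36, SE 0.10), also adjusted over the list alone, and the list was not called (camera adjusted p = 0.533). Of 17 constitutive 20S core subunits and assembly factors 2 fell, Pomp by 0.50 (SE 0.14) and Psma4 by 0.29 (SE 0.09), neither adjusted over the list alone (camera adjusted p = 0.166). Of 18 subunits of the 19S particle, which feeds substrates to the core, 5 fell and 1 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.473). MHC class II genes rose in 4 of 12 cases and fell in 1, with the same numbers adjusted over the list alone (camera adjusted p = 0.00205, adjusted p = 0.392 with an estimated correlation). H2-Oa rose by 0.78 (SE 0.09), and Ctsl, the cathepsin that cortical cells use for class II peptides, fell by 0.41 (SE 0.12); without cTEC KO 2 this list was not called (camera adjusted p = 0.112). None of Psme1, Pomp, Psma4, H2-Oa and Ctsl passed with a weight per library. Pomp, at 83.7 and 55.9 CPM in the KO libraries and 97.3 and 99.6 in the WT ones, kept its call in 1 of the 4 fits that left out a cTEC library, and Psme1, Psma4 and Ctsl in 3 each. In MHC class I presentation 2 of 12 genes rose, with the same number adjusted over the list alone (camera adjusted p = 0.660).

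Markers of other cell types were measured in the same libraries. Fibroblast and pericyte markers rose in 5 of 10 cases (5 adjusted over the list alone; camera adjusted p = 0.0175, adjusted p = 0.531 with an estimated correlation), among them Pdgfrb (2.19, SE 0.41) and Col1a1 (1.41, SE 0.23). B cell markers rose in 2 of 6 cases (2 adjusted over the list alone; camera adjusted p = 0.0326, adjusted p = 0.456 with an estimated correlation), namely Cd79a and Cd79b. The fibroblast call was lost without cTEC KO 2 or WT 2 (camera adjusted p = 0.668 and 0.224), and the B cell call without cTEC KO 1, KO 2 or WT 1 (0.262, 0.0579 and 0.185). Of 15 dendritic cell and macrophage markers 1 rose, Fcer1g (2.41, SE 0.28; camera adjusted p = 0.268). Of these named markers Pdgfrb passed with a weight per library, and Col1a1, Cd79a, Cd79b and Fcer1g did not. No member passed among 16 thymocyte, 8 endothelial, 5 erythroid and 5 sex-linked genes, with camera adjusted p of 0.325, 0.284, 0.880 and 0.660. The remaining lists were not called in cTEC KO. Members rose and fell, in that order, in 2 and 4 of 20 antioxidant genes, 2 and 1 of 18 unfolded protein response genes, 0 and 3 of 15 autophagy genes, 2 and 1 of 14 p53 targets, 2 and 0 of 22 cell cycle genes, 4 and 4 of 21 chemokine and growth factor genes, and 6 and 3 of 24 adhesion genes. Adjusted over the list alone, 3 and 4 antioxidant, 0 and 1 autophagy, 4 and 5 chemokine and growth factor, and 7 and 3 adhesion genes passed, with no change in the other 3. The median and mean log2 fold change differed in sign for the antioxidant, p53, chemokine and growth factor, and erythroid lists.

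The cTEC libraries varied more than the others, and these group changes stand beside that spread. The biological coefficient of variation was 0.652 among the 4 cTEC libraries, against 0.131 in mTEClo and 0.113 in mTEChi. The KO cTEC libraries correlated with each other at r = 0.895 across genes and the WT ones at r = 0.962, where genes are not independent replicates. In cTEC KO 2, 8541 genes had no reads, against 5757 in cTEC KO 1 and 6108 and 6938 in the WT libraries.

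**Figure D3:**
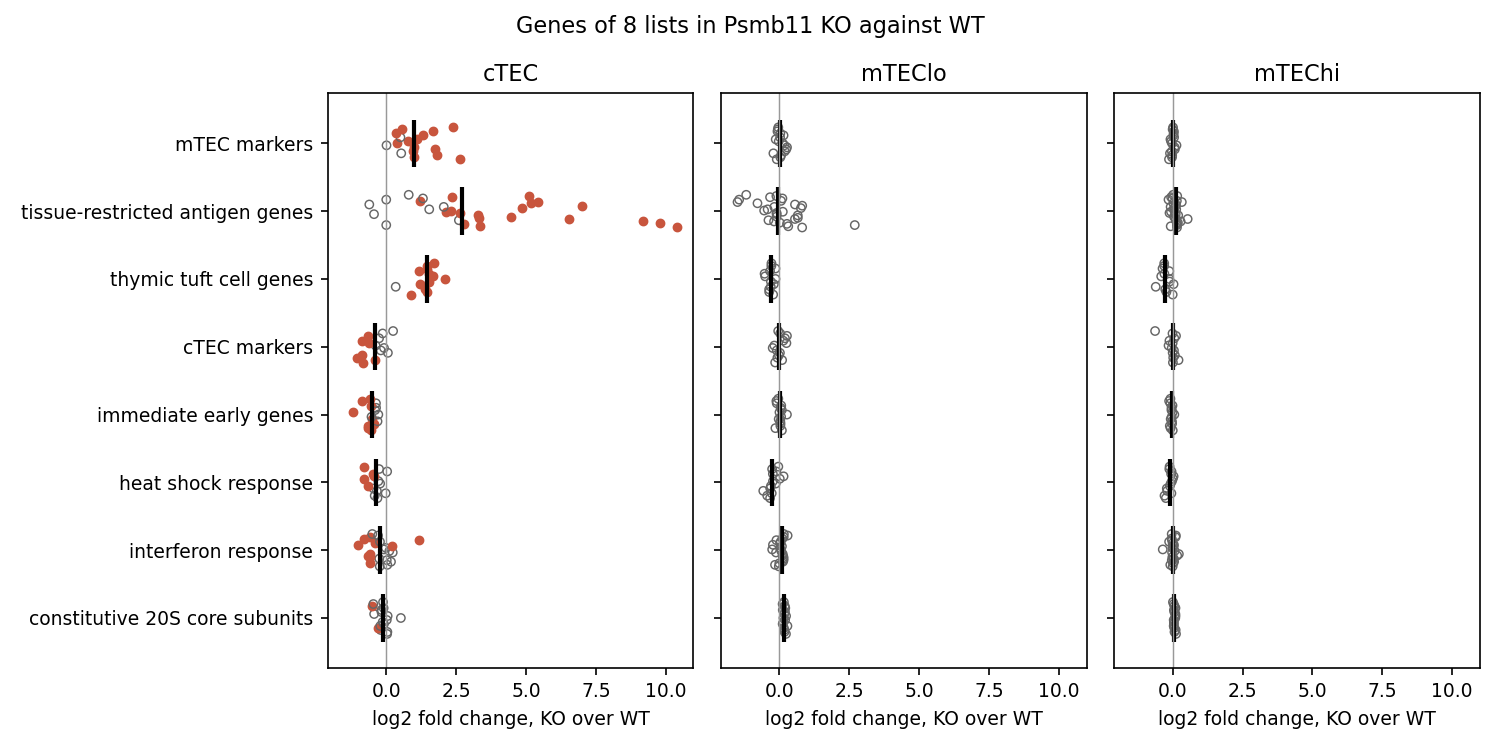
Log2 fold change of KO over WT for each gene of 8 lists in the 3 populations; filled points passed an adjusted p of 0.05 in the shared fit and vertical bars are list medians. Medians in cTEC are 0.98 for medullary markers, 2.71 for tissue-restricted antigen genes and 1.45 for tuft cell genes, and no gene passed in mTEClo or mTEChi.

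**Figure D4:**
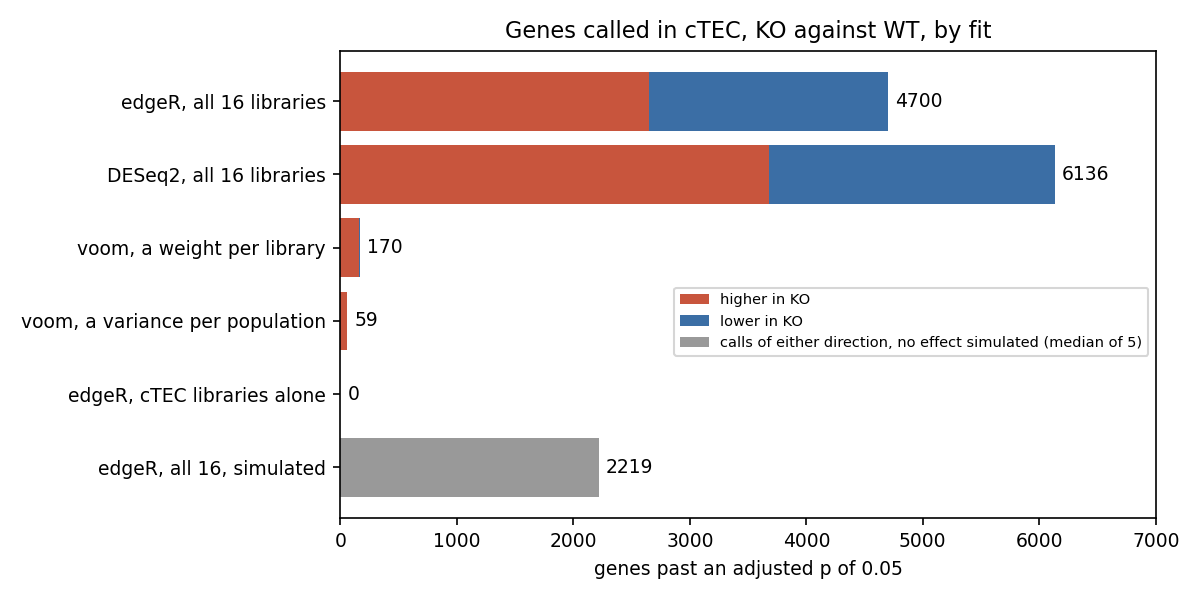
Number of genes past an adjusted p of 0.05 in cTEC, KO against WT, under 5 fits, split into genes higher and lower in KO, with the median count of 5 simulations without an effect in grey. The shared edgeR fit called 4700 genes, DESeq2 6136, the voom fits 170 and 59, the fit of the cTEC libraries alone 0, and the simulations a median of 2219.

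In mTEClo, proteasome genes leaned upward and tuft cell genes downward without Psmb11, by small amounts. The genotypes also differed without overlap in reads in no gene, at 13.7% to 17.4% in mTEClo KO and 17.6% to 19.1% in mTEClo WT. Whether this library difference bears on the small shifts was not tested. All 17 constitutive 20S genes had log2 fold changes above 0, with a median of 0.17 and a camera adjusted p of 5.33e-09 (adjusted p = 0.243 with an estimated correlation), for example Psma5 at 0.29 (SE 0.08, adjusted p = 0.653). All 18 genes of the 19S particle lay above 0 as well (camera adjusted p = 1.03e-04, adjusted p = 0.243 with an estimated correlation), and so did the 5 immunoproteasome and activator subunits (camera adjusted p = 0.00786, adjusted p = 0.296 with an estimated correlation). All 13 tuft cell genes lay below 0, with a median of -0.31 and a camera adjusted p of 2.64e-07 (adjusted p = 0.296 with an estimated correlation), Plcb2 at -0.53 (SE 0.14, adjusted p = 0.653).

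The antioxidant list was higher (camera adjusted p = 5.50e-04, adjusted p = 0.291 with an estimated correlation), with the peroxiredoxin Prdx1 at 0.30 (SE 0.08), and so was the MHC class II list (camera adjusted p = 0.0149, adjusted p = 0.341 with an estimated correlation). The heat shock list was lower (camera adjusted p = 3.23e-05, adjusted p = 0.305 with an estimated correlation), with Hsph1 at -0.58 (SE 0.21). The other 20 lists, medullary and cortical markers, tissue-restricted antigens and the markers of other cell types among them, had camera adjusted p from 0.0772 to 0.981. The 20S, 19S, tuft and heat shock calls held with each mTEClo library left out. The immunoproteasome call was lost without KO 3 (camera adjusted p = 0.0778), the MHC class II call without KO 1 or KO 3 (0.0527 and 0.153) and the antioxidant call without KO 2 (0.0873).

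No single gene passed the shared fit in mTEClo, not even Psmb11, so its count of 0 does not show an absence of effect. The edgeR count was 0, with 1302 genes at an unadjusted p under 0.05, the DESeq2 Wald test called 49, and voom called 94 with a weight per library and 16 with a variance per population. Adjusted over the list alone, 2 of the 20S genes, 1 tuft cell gene and 1 antioxidant gene passed. The smallest adjusted p of the shared fit was 0.444, for the calcium-activated chloride channel gene Ano2 and for Rgs9, a regulator of G-protein signalling. Ano2 had 0 counts in KO and 31 in WT, at least 11.7-fold lower, and Rgs9 a log2 fold change of -0.43 (SE 0.07). Dscaml1, higher in cTEC KO, stood at -0.48 here (SE 0.09, adjusted p = 0.587). With a weight per library Dscaml1, Rgs9, Plcb2 and Prdx1 passed (adjusted p = 0.00343, 0.00625, 0.0313 and 0.0463), and with the DESeq2 Wald test Dscaml1, Rgs9 and Plcb2 (0.00114, 2.52e-06 and 0.0488).

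In mTEChi, tuft cell genes again lay low without Psmb11, 11 of 13 below 0 with a median of -0.26 and a camera adjusted p of 3.76e-07 (adjusted p = 0.552 with an estimated correlation), Plcb2 at -0.30 (SE 0.14). Reads in no gene were again lower in KO, at 19.8% to 22.4% against 23.2% to 23.7% in WT, and their bearing on the list shifts was not tested. The 20S genes lay above 0 in 17 of 17 cases, with a median of 0.06 and a camera adjusted p of 0.00164 (adjusted p = 0.552 with an estimated correlation). With estimated-correlation adjusted p of 0.552 each, the antioxidant list was higher (camera adjusted p = 0.00116), heat shock lower (camera adjusted p = 0.00164), adhesion higher (camera adjusted p = 0.0325, with the laminin gene Lamb3 at 0.33, SE 0.08) and sex-linked genes higher (camera adjusted p = 0.0284). Members of the sex-linked list went opposite ways. The Y-linked Uty stood at 0.41 (SE 0.24), while Xist had 854, 957 and 1284 CPM in KO against 1276, 1411 and 1209 in WT. Thymocyte markers were higher too (camera adjusted p = 0.0121, adjusted p = 0.851 with an estimated correlation), all 16 of them above 0. Of these calls only the antioxidant one held with each library left out. The tuft cell call was lost without WT 3 (camera adjusted p = 0.224), the 20S call without KO 1 or WT 3 (0.539 and 0.0761) and heat shock without KO 1, WT 2 or WT 3 (0.541, 0.101 and 0.271). The adhesion call was lost without KO 2, KO 3, WT 1 or WT 2 (0.526, 0.589, 0.293 and 0.130) and the sex-linked one without KO 1, KO 3, WT 1 or WT 3 (0.0887, 0.0517, 0.0771 and 0.138). Thymocyte markers were called in the other direction without KO 1 (0.0310) and not called without WT 2 or WT 3 (0.391 and 0.435). The other 20 lists had camera adjusted p from 0.0551 to 0.957.

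No gene passed the shared fit in mTEChi, not even Psmb11. The edgeR count was 0, with 121 genes at an unadjusted p under 0.05, the DESeq2 Wald test called 0, and voom called 5 with a weight per library and 1 with a variance per population. With no effect, a share of 0.05 of the 20126 genes would be expected under that p, which is more than 121. The biological coefficient of variation was 0.274 in the shared fit and 0.113 among the mTEChi libraries. The edgeR count of 0 therefore does not show an absence of effect. The growth factor receptor adaptor Grb10, at -0.45 (SE 0.09), and the Deltex ligase Dtx4, at 0.40 (SE 0.09), had the smallest p-values after Psmb11, each with an adjusted p of 1. With a weight per library Grb10 and Lamb3 passed (adjusted p = 0.00787 and 0.0252). Adjusted over the list alone, 1 adhesion gene passed and no member of the other lists did.

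The effects of Psmb11 loss were then set against each other by testing the differences. The effect in cTEC exceeded that in mTEClo for S100g (log2 difference 3.73, SE 0.19), Iapp (5.23, SE 0.27), Cd52 and Dscaml1 (2.46, SE 0.14, from 1.98 in cTEC and -0.48 in mTEClo), and that in mTEChi for S100g (4.11, SE 0.19), Iapp, Cd52 and Fcer2a. Isoc1 was lower in both differences, and these 6 genes also passed with a weight per library. The shared fit called 2676 genes for cTEC minus mTEClo (1556 higher, 1120 lower) and 2160 for cTEC minus mTEChi (1351 higher, 809 lower), and the fit with a weight per library 229 and 176. On simulated data the shared fit called 1042 and 1006 unchanged genes for these differences. The first count was 7598 without cTEC KO 1, 4530 without cTEC KO 2 and 1625 to 1777 without mTEClo KO 2, WT 1 or WT 2, and the second 7327 without cTEC KO 1, 4184 without cTEC KO 2 and 1308 to 1367 without mTEChi KO 2, KO 3, WT 1 or WT 3. For mTEChi minus mTEClo edgeR called 0, with 314 genes at an unadjusted p under 0.05, the DESeq2 Wald test called 2 and both voom fits called 0. The 314 genes were fewer than the share of 0.05 expected of 20126 genes with no effect, so the edgeR count of 0 does not show equal effects.

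Which genes part the 3 sorted populations was asked of the WT libraries. Against WT mTEClo, WT cTEC were higher in Scn1a (log2 fold change 5.12, SE 0.15), in Cd83, a regulator of surface MHC class II (4.51, SE 0.15), in Kitl (3.62, SE 0.13) and in the osteoglycin gene Ogn (5.81, SE 0.44). They were lower in Iapp (-6.69, SE 0.24) and in the sodium channel subunit Scn3b (-3.48, SE 0.13). The kallikrein protease genes Klk13 and Klk6 had 0 counts in WT cTEC and were at least 466-fold and 377-fold lower there. These bounds cover counting error only. Genes with 1 to 2 CPM in the other cTEC libraries were at 0 in 3.96% of cases in cTEC WT 1 and 10.8% in cTEC WT 2, so true folds may be smaller.

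Of 14 cortical markers 12 were higher in cTEC and 0 lower (12 and 1 adjusted over the list alone; camera adjusted p = 1.11e-32, adjusted p = 0.00308 with an estimated correlation), among them the chemokine gene Ccl25 (3.83, SE 0.22). Of the 21 chemokine and growth factor genes 13 were higher and 2 lower (camera adjusted p = 7.33e-09, adjusted p = 0.00308 with an estimated correlation). Of 17 medullary markers 13 were lower (camera adjusted p = 1.25e-11, adjusted p = 0.0348 with an estimated correlation), among them the keratin gene Krt14 (-1.68, SE 0.11). Tuft cell genes were lower in 12 of 13 cases (camera adjusted p = 3.53e-22, adjusted p = 0.0348 with an estimated correlation), cornified cell genes in 11 of 11 (camera adjusted p = 1.08e-09, adjusted p = 0.0619 with an estimated correlation) and tissue-restricted antigens in 16 of 28 (camera adjusted p = 1.39e-08, adjusted p = 0.108 with an estimated correlation). Adjusted over the list alone, 13 tuft cell genes and 18 tissue-restricted antigens were lower, and the counts of the medullary, cornified and chemokine lists did not change. The other 21 lists had camera adjusted p from 0.0601 to 0.893. The shared fit called 6847 genes (3149 higher, 3698 lower), of which 991 and 2296 differed at least 2-fold, and the voom fit with a variance per population called 2986.

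Against WT mTEChi, WT cTEC were higher in Scn1a (7.55, SE 0.17), in the hedgehog co-receptors Gas1 (6.40, SE 0.12) and Boc (4.40, SE 0.09), in the chemokine gene Cxcl12 (5.58, SE 0.19), in Il7, the survival cytokine of thymocytes (2.40, SE 0.09), and in Ctsl (4.13, SE 0.12). They were lower in the hormone gene Fgf21 (-6.30, SE 0.14), in Cd52 (-4.60, SE 0.11) and in Hdc (-6.41, SE 0.25). Cytl1, Mybpc3, Klk6, Retnla and Klk5 had 0 counts in WT cTEC and were at least 1799-fold, 1701-fold, 1520-fold, 1473-fold and 1422-fold lower. These bounds also cover counting error only, and genes lost from the WT cTEC libraries could make the true folds smaller.

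Tissue-restricted antigens were lower in 28 of 28 cases (camera adjusted p = 3.42e-07, adjusted p = 0.163 with an estimated correlation), cell cycle genes in 22 of 22 (camera adjusted p = 3.72e-06, adjusted p = 0.163 with an estimated correlation) and medullary markers in 15 of 17, with 2 higher (camera adjusted p = 2.64e-09, adjusted p = 0.0783 with an estimated correlation). Cornified cell genes were lower in 11 of 11 cases (camera adjusted p = 0.00133, adjusted p = 0.332 with an estimated correlation), and MHC class II genes in 9 of 12, with 2 higher (camera adjusted p = 1.84e-04, adjusted p = 0.163 with an estimated correlation). Interferon response genes were higher in 19 of 22 cases with 2 lower (camera adjusted p = 1.92e-14, adjusted p = 0.0174 with an estimated correlation), immediate early genes in 15 of 15 (camera adjusted p = 7.69e-08, adjusted p = 0.251 with an estimated correlation) and cortical markers in 9 of 14, with 1 lower (camera adjusted p = 6.51e-07, adjusted p = 0.163 with an estimated correlation). Chemokine and growth factor genes were higher in 11 cases and lower in 7 (camera adjusted p = 4.17e-04, adjusted p = 0.0783 with an estimated correlation). Adjusted over the list alone, 2 cortical markers were lower, and the other counts did not change. The other 18 lists had camera adjusted p from 0.0519 to 0.991. The shared fit called 14149 genes, 6217 higher and 7932 lower. Scaling by DESeq2 size factors shifted the median log2 fold change by -0.21 and the share of calls that were higher from 43.9% to 35.1%.

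WT mTEChi exceeded WT mTEClo in Cd52 (4.98, SE 0.09), in the class II beta chain gene H2-Eb2 (1028 against 64.3 CPM), in Cd80 (4.34, SE 0.12), in Hdc (5.88, SE 0.20) and in the tissue-restricted genes Csn2 (5.76, SE 0.28) and Spt1 (5.27, SE 0.41). The scavenger receptor gene Marco, Fam26d and the cytokine gene Il9 had 0 counts in WT mTEClo and were at least 1530-fold, 740-fold and 626-fold higher. Gas1 (-5.25, SE 0.11), Boc (-4.49, SE 0.09), the matrix Gla protein gene Mgp (-4.57, SE 0.13) and the complement gene C1s (-3.98, SE 0.08) were lower.

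MHC class II genes were higher in 10 of 12 cases and lower in 1 (camera adjusted p = 9.65e-09, adjusted p = 0.0530 with an estimated correlation), cell cycle genes in 22 of 22 (camera adjusted p = 5.80e-10, adjusted p = 0.0621 with an estimated correlation), tissue-restricted antigens in 23 of 28 with 2 lower (camera adjusted p = 0.00155, adjusted p = 0.389 with an estimated correlation) and medullary markers in 14 of 17 with 3 lower (camera adjusted p = 5.89e-04, adjusted p = 0.241 with an estimated correlation). Dendritic cell and macrophage markers were higher in 13 of 15 cases with 1 lower (camera adjusted p = 0.0274, adjusted p = 0.370 with an estimated correlation). Interferon response genes were lower in 20 of 22 cases with 1 higher (camera adjusted p = 1.11e-20, adjusted p = 0.00633 with an estimated correlation). With estimated-correlation adjusted p of 0.241 each, tuft cell genes were lower in 13 of 13 cases (camera adjusted p = 1.88e-07), immediate early genes in 15 of 15 (camera adjusted p = 5.80e-10) and adhesion genes in 15 of 24 with 7 higher (camera adjusted p = 2.21e-04). Adjusted over the list alone, 24 tissue-restricted antigens were higher, and the other counts did not change. The other 18 lists had camera adjusted p from 0.124 to 0.997. The shared fit called 13385 genes, 7258 higher and 6127 lower (54.2% higher). With DESeq2 size factors the median log2 fold change shifted by 0.19 and the share higher was 64.2%.

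The number of genes detected, a measure of how broadly a population transcribes its genome, was compared between populations and between genotypes. Genes lost from a library lower it too. Genes with 1 to 2 CPM in the other cTEC libraries were at 0 in 3.96% of cases in cTEC WT 1 and 10.8% in cTEC WT 2. The lower WT cTEC numbers therefore cannot be read as breadth alone, and this share was not computed in mTEC. WT mTEChi libraries detected 20778 ± 144 genes (n = 3), WT mTEClo 18462 ± 239 (n = 3) and WT cTEC 16843 ± 583 (n = 2). Each of the 3 differences between WT populations had an exact permutation p of 0.1, the smallest these group sizes allow. With at least 5 counts required of a gene, the difference of WT cTEC from WT mTEClo was -940.4 in place of -1619. KO libraries detected 20837 ± 141 genes in mTEChi (n = 3, exact permutation p = 0.5), 18356 ± 146 in mTEClo (n = 3, exact permutation p = 0.7) and 16258 ± 1969 in cTEC (n = 2, exact permutation p = 1, where the smallest possible is 0.333). The cTEC difference of KO from WT was -1977 without cTEC KO 1 and 807 without cTEC KO 2. Adjusted over these 6 comparisons, the p-values were 0.2 between WT populations and 0.75, 0.84 and 1 between genotypes.

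**Figure D5:**
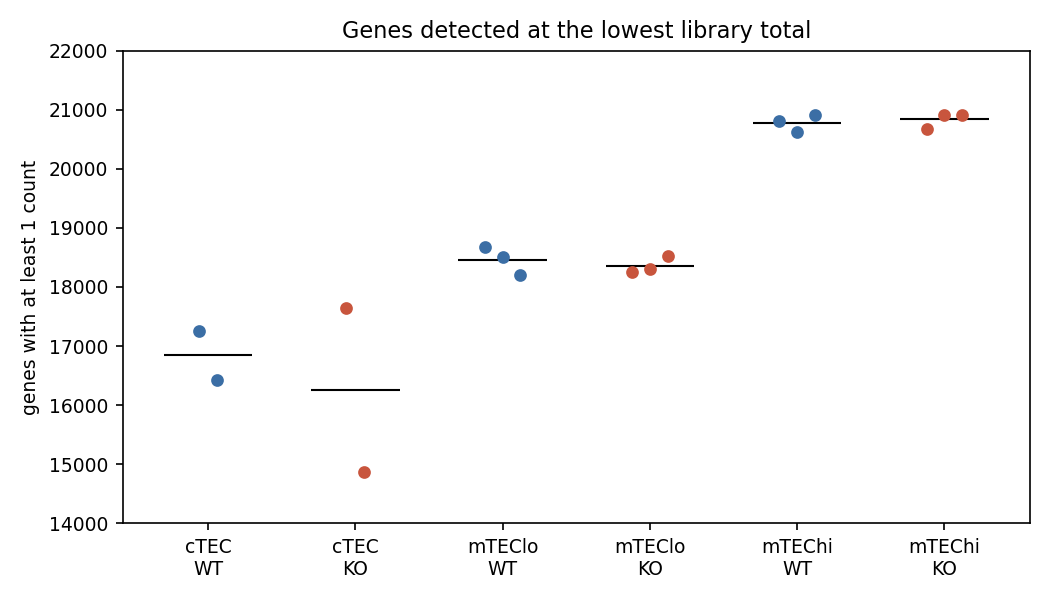
Genes with at least 1 count in each library after thinning to the lowest total, by population and genotype, on an axis that does not start at 0; points are libraries and bars are group means. WT means are 16843 in cTEC, 18462 in mTEClo and 20778 in mTEChi, and the cTEC KO libraries lie at 17650 and 14866.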

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

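The tests of mTEClo and mTEChi cells in the cTEC KO libraries, of sequencing depth and of RNA molecules behind cTEC KO 2 were chosen only after the results were seen; the tests of the spread among the cTEC libraries and of other splits were written before.

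What set the following results apart is a tested difference between populations in the effect of Psmb11 loss. The effect in cTEC differed from that in mTEClo for 2676 genes and from that in mTEChi for 2160 in the shared fit, which on simulated data called 1042 and 1006 unchanged genes, while the fit with a weight per library called 229 and 176. Against mTEClo, it was higher in S100g (adjusted p = 2.41e-07, edgeR), Iapp (2.41e-07), Dscaml1 (9.12e-07) and Cd52 (5.02e-06), and lower in Isoc1 (1.42e-04), 5430402O13Rik (1.62e-04), Adam7 (2.00e-04) and Pcdhb3 (2.06e-04). Against mTEChi, it was higher in S100g (8.75e-08), Iapp (4.75e-07), Cd52 (1.24e-06) and Fcer2a (5.67e-06), and lower in Isoc1 (2.36e-04), 5430402O13Rik (1.57e-04) and Pcdhb3 (2.15e-04). The 3 genes 5430402O13Rik, Adam7 and Pcdhb3 had 0 counts in both cTEC KO libraries and reached at most 1.40 CPM in the cTEC WT ones, and did not pass with a weight per library.

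By camera, the effect in cTEC lay above that in mTEClo for medullary markers (adjusted p = 1.00e-11), tissue-restricted antigens (4.94e-13), tuft cell genes (9.91e-18) and cornified cell genes (7.15e-04), and below it for cortical markers (6.44e-04), 20S subunits (0.00124), interferon response (0.00586) and immediate early genes (5.15e-05). With an estimated correlation none of these was called, with adjusted p from 0.0773 to 0.471. Against mTEChi, it lay above for medullary markers (9.09e-14), tissue-restricted antigens (1.80e-13), tuft cell genes (1.74e-16), cornified cell genes (0.00322), MHC class II (0.0117), B cell markers (0.0236) and fibroblast markers (0.0151), and below for cortical markers (6.43e-04), 20S subunits (0.0309), heat shock (0.0218), interferon response (0.0127) and immediate early genes (1.69e-04). With an estimated correlation these had adjusted p from 0.0668 to 0.600. The effect in mTEChi lay below that in mTEClo for 20S subunits (0.00106), 19S subunits (0.0385) and fibroblast markers (0.0385), each with an adjusted p of 0.696 with an estimated correlation.

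The rise of medullary, tissue-restricted and tuft cell genes in cTEC KO may reflect medullary cells, or their RNA, in those libraries, although the sort on Ly51 and UEA1 should remove them. RNA of mTEClo would bring all abundant mTEClo genes. The median of 40 such genes rose by 32.6% of the way to mTEClo in cTEC KO 1 and 16.9% in cTEC KO 2, beside 39.5% and 24.9% for the tuft cell genes. In both libraries 20% of them (8 genes, for example Tgfbi and Cxcl14) stayed below 0.5 of the tuft share. Of these, 1 lay more than 2 SDs of the cTEC libraries below the full share with the mean variance of the 40 genes and 7 with the median variance, so mTEClo RNA cannot be told apart from this spread, and whole mTEClo or a subset such as tuft cells stay open. RNA from mTEChi alone falls short for the tuft cell genes, whose median level was at least 2.22 times what the mTEChi share allows in each KO library. For 420 mTEChi genes, 62.9% lay above their WT cTEC mean in cTEC KO 2 and 96.7% in cTEC KO 1, against 54.5% and 43.8% in each WT library measured against the other, so mTEChi RNA in cTEC KO 2 cannot be told apart from the spread between libraries. Both WT values come from the same pair of libraries. Genes with 1 to 2 CPM in the other cTEC libraries were at 0 in cTEC KO 2 in 35.7% of cases. Such losses would lower its value, so the test cannot exclude mTEChi RNA there. A mixture of both medullary populations and a change of the KO cTEC themselves, the explanation that the design offers, were not tested and stay open.

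Genes without reads in cTEC KO 2 set that library apart. Lower sequencing depth was excluded, since 1565 more genes were undetected there than in the next cTEC library with all libraries at the same total. A small number of RNA molecules behind the library is consistent with what was found: genes with 1 to 2 CPM in the other cTEC libraries were at 0 in cTEC KO 2 in 35.7% of cases, 3.30 times the 10.8% of cTEC WT 2. Whether the KO thymus yields fewer cTEC, which could lower the RNA, was not tested, as cell numbers are not given.

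The genes called in cTEC by the shared fit may come in large part from spread among the cTEC libraries that the shared estimate leaves out. With no effect simulated, that fit called a median of 2219 genes. The other ways to part the 4 cTEC libraries into pairs called 1226 and 484 genes, against 4700 for KO and WT, so these pairings did not give as many. With 3 pairings the share cannot fall under 0.05. A pairing that mixes genotypes would hold any KO effect within its pairs, and whether that lowers its count was not tested, so the lower counts do not exclude spread as the source. A KO effect beyond this spread stays open for the 170 genes that passed in both fits.

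In mTEClo and in mTEChi, the real split of the 6 libraries called 0 genes and the highest other split 0, with 10 of 10 splits as large. No split can give fewer than 0, so these counts say nothing about chance, and 10 splits are too few for a share under 0.05. For WT mTEChi against WT mTEClo the real split called 13385 genes and the highest other 0, which is 1 of 10 splits, again too few. For the difference between mTEChi and mTEClo the count says nothing about chance either, as the real value was 0, the highest other 0, and 100 of 100 splits gave as many.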

How the results depend on the processing

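The voom fits were chosen after seeing the data; all other alternatives were planned before the data were examined. Fits of the groups compared alone drop the other libraries' information on the spread, and voom gives noisy libraries less weight; for all other changes below the cause was not tested. In the groups compared alone, the counts were 0 in cTEC, 1 in mTEClo, 1 in mTEChi, 834 for cTEC minus mTEClo, 1070 for cTEC minus mTEChi and 2 for mTEChi minus mTEClo. With a weight per library they were 170, 94, 5, 229 and 176, and with a variance per population 59, 16, 1, 83 and 61, with 2986 for WT cTEC against WT mTEClo. The DESeq2 Wald test called 49 in mTEClo, 4122 and 3756 for the differences of cTEC from mTEClo and mTEChi, and 2 for mTEChi minus mTEClo. On log2(RPKM + 1), limma called 1 in mTEClo and 1 in mTEChi, and without a filter on RPKM 2 and 36. The log2 fold change of Psmb11 lost its call in cTEC at -7.19 with the cTEC libraries alone, -9.55 with a weight per library and -10.14 with a variance per population, and gained one at -2.93, -3.03 and -2.91 in mTEClo and -3.35, -3.27 and -3.39 in mTEChi.

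Leaving out each library gave 2636 to 8769 genes in cTEC, 1625 to 7598 for cTEC minus mTEClo and 1308 to 7327 for cTEC minus mTEChi, where a group left with 1 library is taken to vary like the others. The difference in genes detected ranged from -2031 to -1207 for WT cTEC minus mTEClo and from -4347 to -3523 for WT cTEC minus mTEChi. With at least 5 counts it was -940.4, -3574 and, for mTEChi minus mTEClo, 2633. The log2 fold change of Sprr1b in cTEC ranged from -2.42 without cTEC KO 1, where its direction turned, to 10.12. Thymocyte markers in mTEChi had camera adjusted p from 1.26e-08 to 0.435 and turned direction without mTEChi KO 1 (0.0310). Other libraries left out reversed no call of a named gene or list. The difference in genes detected between cTEC KO and WT, not called, ranged from -1977 to 807.

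Of 254 values of named genes, 252 kept direction and call with DESeq2 size factors and 254 with no filter. A call was lost by 91 of 249 in the groups compared alone, 78 of 254 with a weight per library and 96 of 254 with a variance per population, and gained by 0, 6 and 2, and by 6 of 244 with the DESeq2 Wald test, which lost 0. The replicate block, with 4056 genes in cTEC, kept 246 of 254 such values and 72 of 81 list results. Whether the replicate numbers pair the samples cannot be told from 2 or 3 libraries per group. Deviations of KO and WT libraries with the same number correlated at -0.0123 to 0.0751. The KO libraries correlated best with the WT library of their own number, except mTEClo KO 3 and mTEChi KO 2. With 2 libraries per group, deviations mirror each other, so both cTEC values (0.0751) are the same comparison and not separate matches. DESeq2 gave no adjusted p for Psmb11 in mTEClo. With a library left out, 30 of 432 list results lost a call and 22 gained one, as did 50 and 5 of 1358 values of named genes. Of the 25 list calls between KO and WT, 25 were lost with an estimated correlation and 12 with fry.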

Other observations

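The test of a common KO effect in the medullary populations was written before its result was seen. The X-inactivation RNA Xist and the Y-linked Ddx3y were both present in every library, between 130 and 1571 CPM and between 29.4 and 109 CPM. Xist stood at 130 and 719 CPM in the cTEC KO libraries and at 1571 and 716 CPM in the cTEC WT ones, and Ddx3y at 109 and 66.6 against 45.8 and 101 CPM. In mTEClo Xist stood at 713, 653 and 930 CPM in KO and at 962, 1179 and 1062 CPM in WT, without overlap (log2 fold change -0.48, SE 0.43). In mTEChi it stood at 854, 957 and 1284 CPM in KO and at 1276, 1411 and 1209 CPM in WT, with overlap. The labels give no sex. Whether the mix of sexes differed between genotypes was not tested, and such a difference could not be told apart from loss of Psmb11.

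All 22 cell cycle genes were higher in WT mTEChi than in WT mTEClo with a median log2 fold change of 3.06, whereas KO against WT had medians of 0.09 in mTEChi and 0.12 in mTEClo, with 0 genes past the threshold in each. For the 15 immediate early genes the corresponding medians were -1.84, -0.04 and 0.03. The medians were not tested against each other, and with an estimated correlation neither list was called between the WT populations (adjusted p = 0.0621 and 0.241).

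The hypothesis that loss of Psmb11 has a common effect in both medullary populations was tested by correlating the KO effects of mTEClo and mTEChi across 20125 genes other than Psmb11. The correlation was 0.0529, and other splits of the libraries reached 0.0701 in size, with 5 of 100 splits as large as the real one. Chance cannot be excluded, so a common effect is not borne out across all genes, where genes are not independent replicates.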
